A study of Rattus norvegicus with 7 samples.

How the data were processed

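RNA sequencing was analysed from cultured rat oligodendrocyte progenitor cells, the precursors of the myelinating cells of the central nervous system, isolated from brains at postnatal day 7. Per the labels' protocols, about 40000 cells went into each well of plates with 12 wells and were transfected with a control siRNA or with an siRNA against RNLTR12-int, an endogenous retroviral sequence of the rat genome, and kept in differentiating medium for 4 to 5 days. Total RNA (RNA integrity numbers 9 to 10) was depleted of ribosomal RNA and made into directional paired-end libraries, per the labels' protocols. The labels give 4 control libraries and 3 siRNLTR12-int libraries and call them biological replicates, without naming an animal, culture or day for any of them. The p-values therefore measure the spread between these samples, which may in part be technical.

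The submitters' processing notes name Salmon, DESeq2 and the genome build Rnor_6.0, with no versions. The authors deposited a table of normalised gene counts (a signal per gene and library, scaled by 1 size factor per library) and a table of their own comparison. In the comparison table the authors gave the mean signal, the log2 fold change of siRNLTR12-int over control with its standard error, a Wald-type test score, the p-value and the adjusted p-value, per the file headers. Gene identifiers and symbols were taken from these tables, in which 33 of 32852 genes had no symbol. The reference table at hand was of another rat assembly and held no matching identifiers, so no coordinates are given. In each library, 100% of the values above 0 were whole multiples of 1 step (tolerance 0.01 of a step), which gave back whole numbers of reads. Whole numbers of this kind also result when estimated counts are rounded, and how multi-mapped reads were divided between related genes is not given in the sources used here, so values of near-identical gene copies are uncertain. RNLTR12-int was not analysed here.

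The recovered reads numbered 41506220, 61803693, 43845904 and 22523873 in control replicates 1 to 4 and 45003358, 31609908 and 48187822 in siRNLTR12-int replicates 1 to 3. The 10 most abundant genes took 10.9% to 12.9% of the reads. No pair of libraries agreed within sampling noise. The closest pair, siRNLTR12-int replicates 2 and 3, had a median chi-square of 1.27 per gene, against 2.74 for the closest control pair (replicates 3 and 4).

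For the main comparison, log2(normalised count + 1) was tested with limma 3.58.1 (empirical Bayes with a mean-variance trend, two-sided) over the 18225 genes with a mean normalised count of at least 10, in all 7 libraries with no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on that log2 scale, which understates the change of low genes. The 23 gene lists, written from textbook knowledge before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 23 lists. They cover structural myelin genes, progenitor markers, newly formed oligodendrocyte markers, lineage transcription factors, inhibitors of differentiation, cholesterol, sphingolipid and fatty acid synthesis, cell cycle, markers of astrocytes, microglia, neurons and vascular cells, interferon, inflammatory, stress and p53 responses, chaperones, mitochondrial transcripts, ribosomal proteins, ion channels, cytoskeleton and RNA-binding proteins. Of these, 6 lists (myelin, progenitor, newly formed, lineage factors, cholesterol, sphingolipid) were set in advance to answer the comparison. Some genes stand in more than 1 list, Mbp and Tppp among them. The level of a list is the mean log2(normalised count + 1) of its members in a library, and levels were compared by a two-sided exact permutation test over the 35 splits of the 7 libraries, whose smallest possible p is 0.0286.

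Genes named in the text follow a rule fixed before the data were examined: Mbp and Sox10; up to 8 rises and 8 falls past the limma test with a mean of at least 100, groups that do not overlap and a symbol that is not provisional (LOC, RGD, AABR or an Ensembl identifier); and the 3 members with the smallest p of each called list, or 2 of each uncalled list among the 6. Since 0 genes passed the limma test, the rise and fall part was also applied to the authors' deposited table, a step added after the data were seen. Any other gene named was chosen after its values were seen. A few genes that the rule selects are not reported here.

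Alternatives fixed in advance were other pseudocounts (0.25 and 8), no filter or a minimum mean of 50, TMM and upper-quartile rescaling, array weights, no trend, a replicate block, each library left out in turn, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, an estimated inter-gene correlation, and fry. Alternatives added after the data were seen were a block for a split of the libraries in astrocyte marker level, that level as a covariate, and a fit of the 4 libraries low in these markers. The tests were tried on simulated counts with known changes. With 7 simulated libraries of the observed spread over 18225 genes, limma called 20.9% of the genes changed 2-fold, 82.1% of those changed 4-fold and 90.9% of those changed 8-fold, with 7 false calls. DESeq2 called 67.2%, 94% and 97% of them with 85 false calls, and edgeR 16.4%, 83.6% and 90.9% with 9 false calls. With 4 simulated libraries of the spread seen among the 4 libraries low in astrocyte markers, limma called 88.1%, 98.5% and 100% with 13 false calls. The simulated genes varied independently and the simulated libraries held no split in astrocyte markers, unlike the real ones. These shares therefore need not hold for the real data. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.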

Results

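The data set holds 7 transcriptomes of differentiating rat oligodendrocyte progenitor cells, 4 transfected with a control siRNA and 3 with an siRNA against the endogenous retroviral sequence RNLTR12-int, at 22523873 to 61803693 recovered reads per library. The comparison asks which transcripts differ when RNLTR12-int is targeted during differentiation, and in particular whether myelin genes do. The level of RNLTR12-int itself was not analysed here, so its knockdown was not checked, and the labels give only the siRNA used.

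Transcripts of major myelin proteins, Mbp, Mag and Mobp among them, were lower in all 3 siRNLTR12-int libraries than in all 4 controls. Mbp (ENSRNOG00000016516), which encodes myelin basic protein, had a normalised count of 167600 ± 156800 (SD, n = 4) in controls and 21990 ± 9001 (SD, n = 3) after the siRNA. The control mean was raised by control replicate 2, at 401820 against 78977 to 109430 in the other controls. In the authors' deposited table (DESeq2) Mbp fell by 2.93 on the log2 scale (adjusted p = 0.00236). With limma the log2 difference of Mbp was -2.63 with a standard error of 0.60, and its adjusted p was 0.647. Over the limma alternatives, edgeR, and DESeq2 on all libraries without a block, the adjusted p of Mbp ranged from 0.00236 to 1. The DESeq2 fits with a block or with fewer libraries were not part of that range. Sox10 (ENSRNOG00000011305), the transcription factor that marks the oligodendrocyte lineage, did not pass either test, with 26960 ± 13040 (SD, n = 4) against 21210 ± 11410 (SD, n = 3) and a log2 difference of -0.35 (limma adjusted p = 0.985).

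The list of structural myelin genes fell as a group. Of its 27 measured members, 22 had a negative log2 difference, the median was -1.18, and the camera test gave an adjusted p of 5.65e-10 (limma, preset correlation), against an adjusted p = 0.638 with an estimated correlation. Lower values passed in 13 members adjusted over the list alone, while 0 members passed over all genes tested with limma, where 14 were lower and 1 higher at an unadjusted p under 0.05. In the authors' deposited table (DESeq2) 9 members fell. They include Mag, an adhesion protein of the myelin sheath (log2 -3.13, adjusted p = 0.00318), Mobp, a protein of compact myelin (log2 -3.77, adjusted p = 0.00236), the tight junction protein Cldn11 (log2 -2.49, adjusted p = 0.00394) and the cytoskeletal protein Ermn (log2 -2.93, adjusted p = 0.00514). Opalin, a membrane protein of oligodendrocytes, fell too (log2 -3.07, adjusted p = 0.0481 in the authors' table, DESeq2). In Mag, Mobp, Cldn11, Ermn and Opalin control replicate 2 was the highest control, which enlarges these falls. Mobp had 25262 normalised counts there, against 3040 to 4965 in the other controls. In 14 members every siRNLTR12-int library lay below every control library, where chance places 5.71% of genes apart in either direction. The level of the list was 11.36 ± 0.594 (SD, n = 4) in controls and 10.13 ± 0.334 (SD, n = 3) after the siRNA, a difference of -1.22 (exact permutation p = 0.0286, the smallest that 35 splits allow; 0.329 after adjustment over 23 lists).

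**Figure D1:**
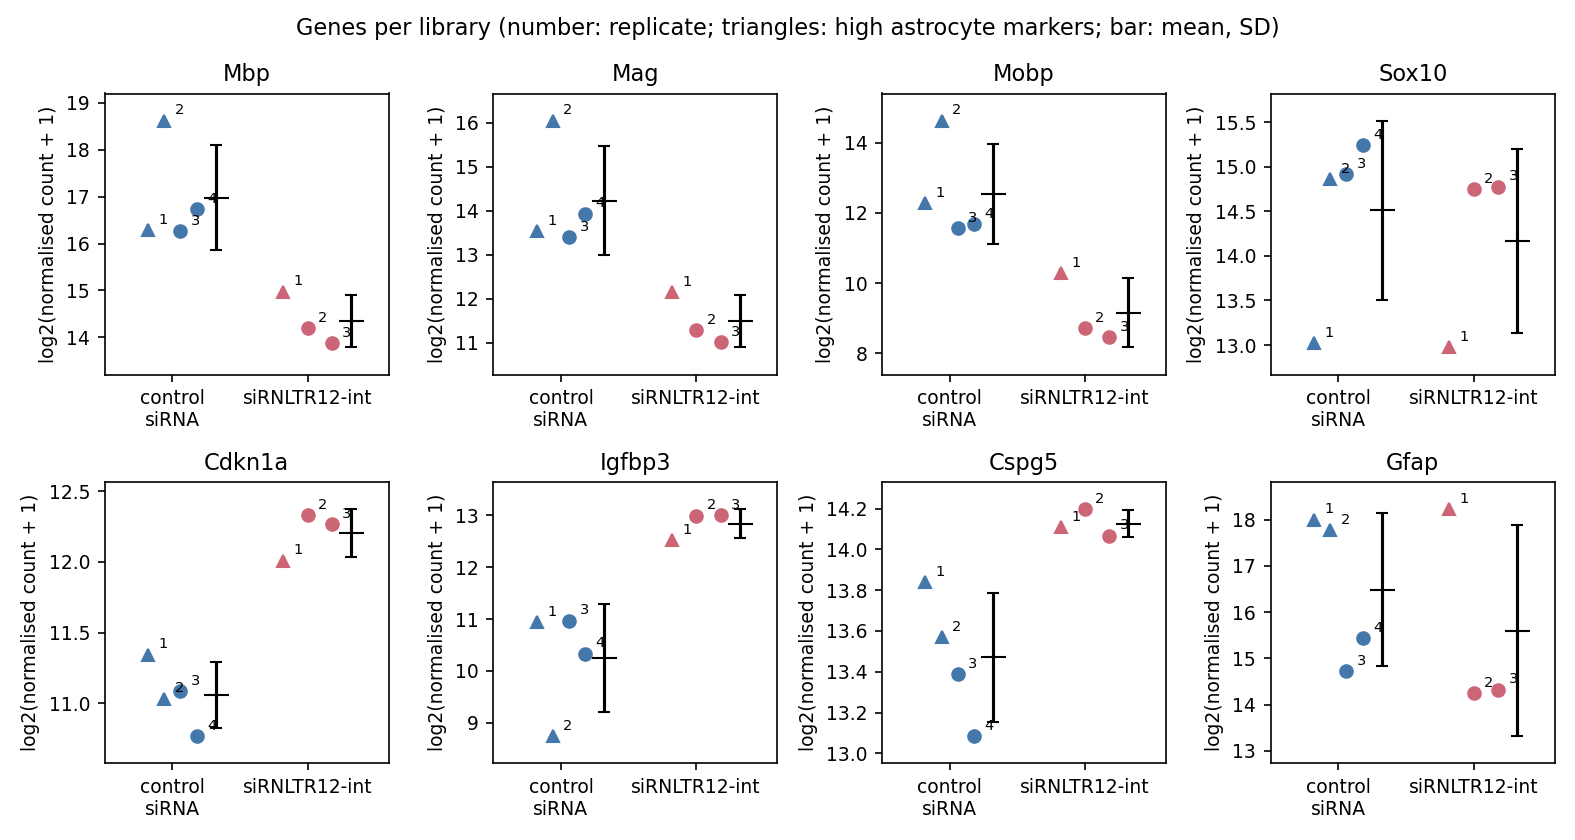
Normalised counts of 8 genes on the log2(count + 1) scale for each library, with the replicate number beside each point, triangles for the 3 libraries high in astrocyte markers, and a bar for the group mean and SD. Mbp, Mag and Mobp lie lower and Cdkn1a, Igfbp3 and Cspg5 higher in the 3 siRNLTR12-int libraries than in the 4 controls, whereas Sox10 and Gfap overlap between the groups.

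Markers of newly formed oligodendrocytes, the stage between progenitor and myelinating cell, also fell as a group. Negative log2 differences were found in 19 of 20 members, with a median of -0.70 and a camera adjusted p of 2.65e-09 (limma), against an adjusted p = 0.638 with an estimated correlation. Adjusted over the list alone, 6 members were lower and 1 was higher, and in the authors' deposited table (DESeq2) 3 fell. Enpp6, a choline phosphodiesterase of new oligodendrocytes, had 6319 ± 5004 (SD, n = 4) normalised counts in controls and 1273 ± 492.8 (SD, n = 3) after the siRNA, and fell by 2.31 on the log2 scale in the authors' table (DESeq2 adjusted p = 0.0125). Its control mean was raised by control replicate 2 (13711, against 3082 to 5068 in the other controls). Kif19 differed by -1.30 (limma adjusted p = 0.661), whereas Samd4a went the other way, with 1832 ± 241.6 (SD, n = 4) against 2533 ± 74.19 (SD, n = 3). The level of the list in control replicate 1, 12.03, lay within the siRNLTR12-int range of 11.84 to 12.13, and the exact permutation p was 0.114.

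Progenitor markers and lineage transcription factors did not pass as lists. Among 19 progenitor markers 12 had a positive log2 difference, with a median of 0.19 and a camera adjusted p of 0.193 (limma). Cspg5, a chondroitin sulfate proteoglycan, had 11560 ± 2516 (SD, n = 4) normalised counts in controls and 17870 ± 823.5 (SD, n = 3) after the siRNA (log2 0.65, limma adjusted p = 0.661), and Xylt1, which starts glycosaminoglycan chains, differed by 0.59 (limma adjusted p = 0.875). The 24 lineage transcription factors had a median of -0.03 and a camera adjusted p of 0.0837 (limma), with 2 members lower adjusted over the list alone. These were St18 and Nkx6-2, which fell by 2.19 and 2.07 on the log2 scale in the authors' deposited table (DESeq2 adjusted p = 0.00876 and 0.014). In St18 and Nkx6-2 control replicate 2 was the highest control, which enlarges these falls. St18 had 1659 normalised counts there, against 424 to 614 in the other controls. Without siRNLTR12-int replicate 1 the camera adjusted p of the progenitor list became 0.00737, and without control replicate 1 that of the lineage factors became 0.00448. Leaving out control replicate 4 also took the progenitor list past the threshold (0.0399), and leaving out siRNLTR12-int replicates 2 or 3 did so for the lineage factors (0.00718 and 0.0177).

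The sphingolipid and galactolipid list fell, with 15 of 20 members negative, a median of -0.23 and a camera adjusted p of 0.00144 (limma), against an adjusted p = 0.663 with an estimated correlation. No member passed adjusted over the list alone. Cers2, a ceramide synthase, differed by -0.66, Sgms2, a sphingomyelin synthase, by -0.99, and the fatty acid elongase Elovl7 by -1.25 (limma adjusted p = 0.703, 0.772 and 0.784). In Cers2, Sgms2 and Elovl7 control replicate 2 was the highest control, which enlarges these differences. The cholesterol biosynthesis list rose slightly, with 21 of 25 members positive, a median of 0.19 and a camera adjusted p of 0.0204 (limma), against an adjusted p = 0.899 with an estimated correlation. Its members Lss and Insig1 differed by 0.52 and 0.36 (limma adjusted p = 0.841 and 0.854). In the 4 libraries low in astrocyte markers the camera adjusted p of the cholesterol list was 0.296, and it was 0.295, 0.613, 0.499 and 0.227 without control replicate 1, control replicate 2, siRNLTR12-int replicate 2 and siRNLTR12-int replicate 3. The fatty acid synthesis list did not pass (median -0.23, camera adjusted p = 0.264, limma), except with the replicate block (0.038) and in the 4 libraries low in astrocyte markers (0.0206).

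**Figure D2:**
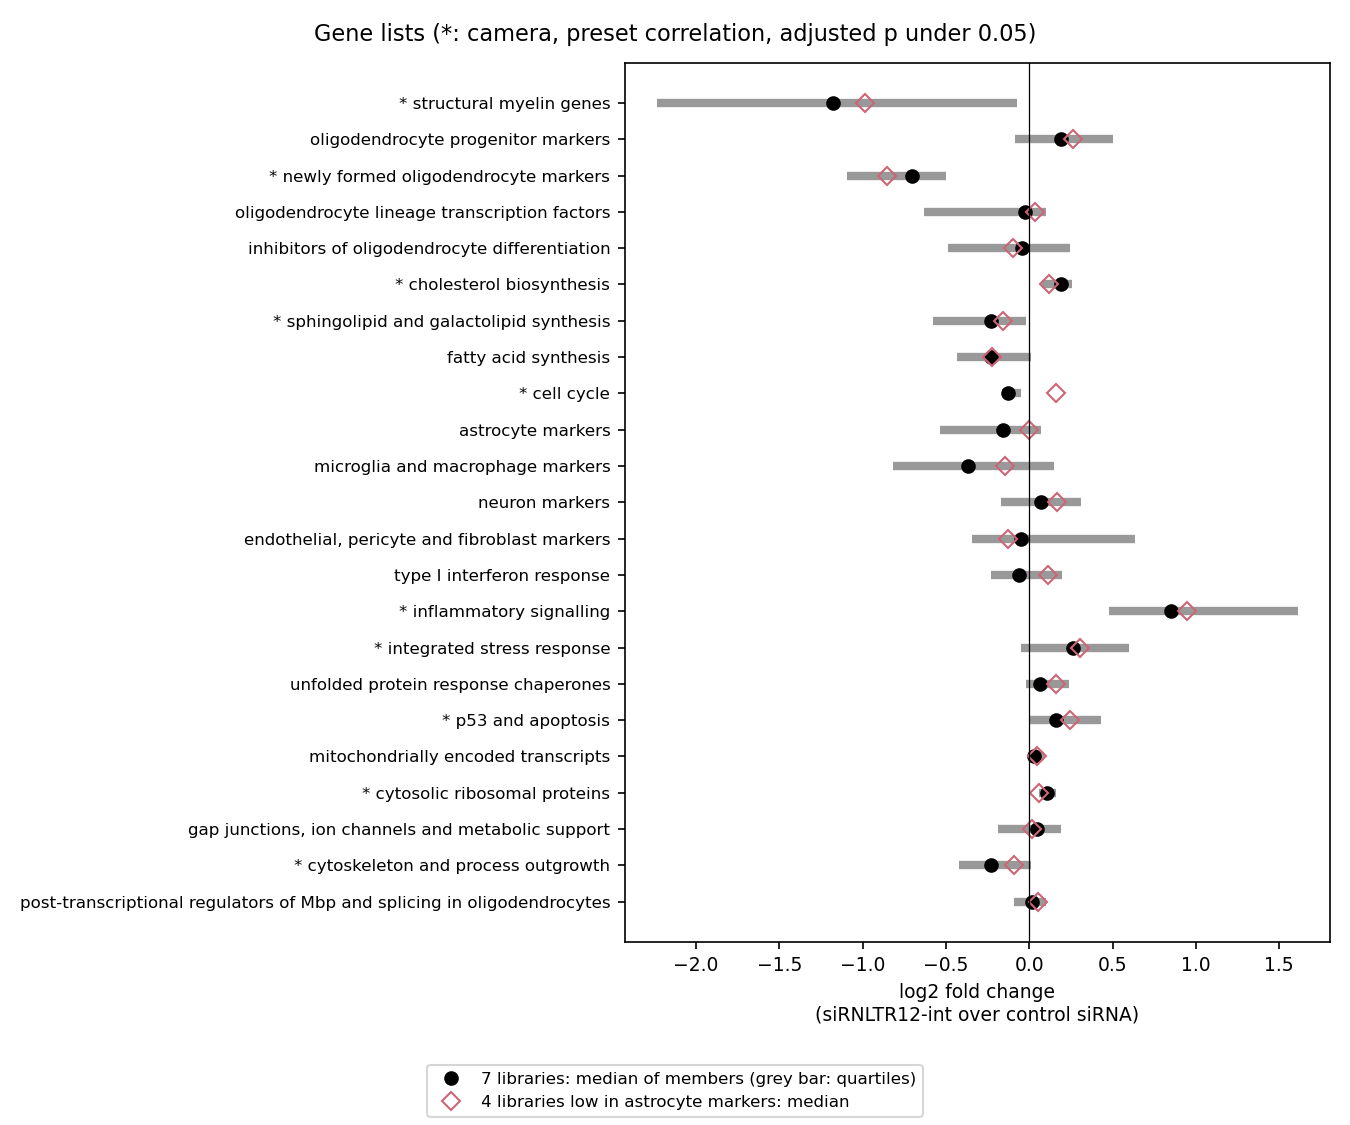
Median log2 fold change of each gene list, siRNLTR12-int over control siRNA, in all 7 libraries (black points, grey bars for the quartiles of the members) and in the 4 libraries low in astrocyte markers (open diamonds), with an asterisk where the camera test passed at the preset correlation. The myelin list lies at -1.18 and -0.98 and the inflammatory list at 0.85 and 0.95, whereas the cell cycle list lies at -0.13 in 7 libraries and 0.16 in 4.

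Genes of p53, stress and inflammatory responses rose as groups in the camera test at the preset correlation. In the p53 and apoptosis list 14 of 19 members were positive, with a median of 0.16 and a camera adjusted p of 0.00147 (limma), against an adjusted p = 0.321 with an estimated correlation, and 3 members were higher adjusted over the list alone. Cdkn1a, the cell cycle inhibitor induced by p53, had 2152 ± 351.1 (SD, n = 4) normalised counts in controls and 4735 ± 542.7 (SD, n = 3) after the siRNA, and rose by 1.14 on the log2 scale in the authors' deposited table (DESeq2 adjusted p = 4.9e-06). Eda2r rose by 0.89 in that table (DESeq2 adjusted p = 0.0289), and Aen differed by 0.62 (limma adjusted p = 0.652). The level of this list was 9.65 ± 0.11 (SD, n = 4) in controls and 9.89 ± 0.055 (SD, n = 3) after the siRNA (exact permutation p = 0.0286, 0.329 after adjustment over 23 lists). In the integrated stress response list 18 of 26 members were positive (median 0.26, camera adjusted p = 0.00023, limma; adjusted p = 0.638 with an estimated correlation), and 2 were higher adjusted over the list alone. The stress cytokine Gdf15 rose by 1.83 and the secreted glycoprotein Stc2 by 1.61 in the authors' table (DESeq2 adjusted p = 0.0074 and 0.0333), and Shmt2, a mitochondrial enzyme of serine metabolism, differed by 0.48 (limma adjusted p = 0.662). Without siRNLTR12-int replicate 1 the camera adjusted p of the stress list was 0.0897. The level of the stress list in control replicate 1 (10.06) lay above siRNLTR12-int replicates 2 and 3 (9.89 and 9.81). Its exact permutation p was 0.2.

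In the inflammatory signalling list 17 of 18 members were positive, with a median of 0.85 and a camera adjusted p of 5.38e-07 (limma), against an adjusted p = 0.663 with an estimated correlation. No member passed adjusted over the list alone, where the smallest adjusted p was 0.0883 (limma). Ptgs2, the inducible cyclooxygenase, had 77.81 ± 43.91 (SD, n = 4) normalised counts in controls and 268.8 ± 45.03 (SD, n = 3) after the siRNA. The cytokine Il1b had 38.17 ± 19.92 (SD, n = 4) against 91.3 ± 16.43 (SD, n = 3), and the chemokine Cxcl1 differed by 2.77 with overlapping groups (limma adjusted p = 0.703). The list was also high in control replicate 1, at a level of 9.16 against 7.31 to 7.56 in the other controls. That level lay above siRNLTR12-int replicates 2 and 3 (8.65 and 8.37), so the groups overlapped, and the exact permutation p was 0.143. Control replicate 1 was also the library with the most microglia marker transcripts (level 10.33).

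The cytoskeleton and process outgrowth list fell (19 of 27 members negative, median -0.23, camera adjusted p = 0.00205, limma; adjusted p = 0.899 with an estimated correlation), with Stmn4 and Tppp, both microtubule regulators, lower in the authors' deposited table (log2 -2.12 and -2.24, DESeq2 adjusted p = 0.0141 and 0.0394). In Stmn4 and Tppp control replicate 2 was the highest control, which enlarges these falls. Stmn4 had 6167 normalised counts there, against 1414 to 2361 in the other controls. Without siRNLTR12-int replicate 1 the camera adjusted p of the cytoskeleton list was 0.217. Cytosolic ribosomal proteins rose by a median of 0.11 (35 of 41 positive, camera adjusted p = 0.0204, limma; adjusted p = 0.899 with an estimated correlation), with Rpl8, Rplp2 and Rpl19 at 0.54, 0.45 and 0.13. That call was lost without control replicates 1 or 2 (0.514 and 0.387), without siRNLTR12-int replicates 2 or 3 (0.502 and 0.612), in the 4 libraries low in astrocyte markers (0.116), and with their split from the other 3 as a block or the astrocyte level as a covariate (0.211 and 0.128). Cell cycle genes fell slightly (median -0.13, 24 of 27 negative, camera adjusted p = 0.0461, limma; adjusted p = 0.899 with an estimated correlation), with Tyms at 0.36, Bub1b at -0.37 and Cenpf at -0.27. That direction turned upward without siRNLTR12-int replicate 1 (camera adjusted p = 0.00371), with array weights (0.0279) and in the 4 libraries low in astrocyte markers (0.00257), and the call was lost without control replicates 1 or 4 (0.328 and 0.0742), with TMM or upper-quartile rescaling (0.0519 and 0.0556), with no mean-variance trend (0.0645), with the replicate block (0.122) and with edgeR (0.0992).

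The remaining lists did not pass with limma in all 7 libraries. Camera adjusted p-values were 0.655 for inhibitors of differentiation, 0.181 for chaperones of the unfolded protein response, 0.655 for mitochondrially encoded transcripts, 0.711 for neuron markers and 0.655 for post-transcriptional regulators of Mbp. The chaperone list passed upward in the 4 libraries low in astrocyte markers (0.00842), with array weights (0.0167), without siRNLTR12-int replicate 1 (0.0113) and without control replicate 2 (0.0469). The neuron list passed upward without siRNLTR12-int replicate 1 (0.0491). In the post-transcriptional list the median was 0.02 and the mean -0.001. The gap junction and ion channel list had a median of 0.05, a mean of -0.30 and a downward test (0.556), in which Gjc3, a connexin, fell in the authors' deposited table (log2 -2.91, DESeq2 adjusted p = 0.0168). The fall of Gjc3 was enlarged by control replicate 2, at 9283 normalised counts against 1323 to 1889 in the other controls. The vascular and fibroblast list had a median of -0.05, a mean of 0.20 and an upward test (0.84). The interferon list had a median of -0.06, a mean of -0.01 and an upward test at an adjusted p of 1. It passed upward with the split of the libraries in astrocyte markers as a block (camera adjusted p = 7.37e-07, limma), with the astrocyte level as a covariate (1.03e-05) and without siRNLTR12-int replicates 2 or 3 (0.0488 and 0.049). It passed downward without siRNLTR12-int replicate 1 (0.000394), and did not pass in the 4 libraries low in astrocyte markers (0.166).

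Astrocyte and microglia markers split the libraries in a way that did not follow the siRNA. Gfap, the intermediate filament of astrocytes, had 262590, 224540 and 306400 normalised counts in control replicates 1 and 2 and siRNLTR12-int replicate 1, against 19440 to 44392 in the other 4 libraries. Astrocyte list levels were 13.06, 12.99 and 13.13 in those 3 libraries and 11.62 to 11.73 in the others. Microglia list levels were 10.33, 8.88 and 9.98 against 7.21 to 7.70. Between the siRNA groups, neither the astrocyte list (median -0.16, camera adjusted p = 0.35) nor the microglia list (median -0.37, camera adjusted p = 0.427) passed with limma. Both passed downward with the replicate block (0.00409 and 0.0014), without siRNLTR12-int replicate 1 (0.000968 and 0.000578) and without control replicate 3 (0.0257 and 0.0347). The astrocyte list also did so without control replicate 4 (0.0399), and the microglia list with array weights (0.0475). The first principal component, with 53.8% of the variance, separated the same 3 libraries from the other 4. Within the 4 libraries low in astrocyte markers the myelin level differed by -1.07, the newly formed level by -0.85 and the p53 level by 0.32. Within the other 3 the differences were -1.19, -0.84 and 0.17, with a single siRNLTR12-int library. In that set the myelin level was 11.15 and 12.24 in control replicates 1 and 2 and 10.51 in siRNLTR12-int replicate 1. The newly formed level was 12.03, 13.33 and 11.84 in the same order. Much of the myelin and newly formed differences there thus rests on control replicate 2.

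**Figure D3:**
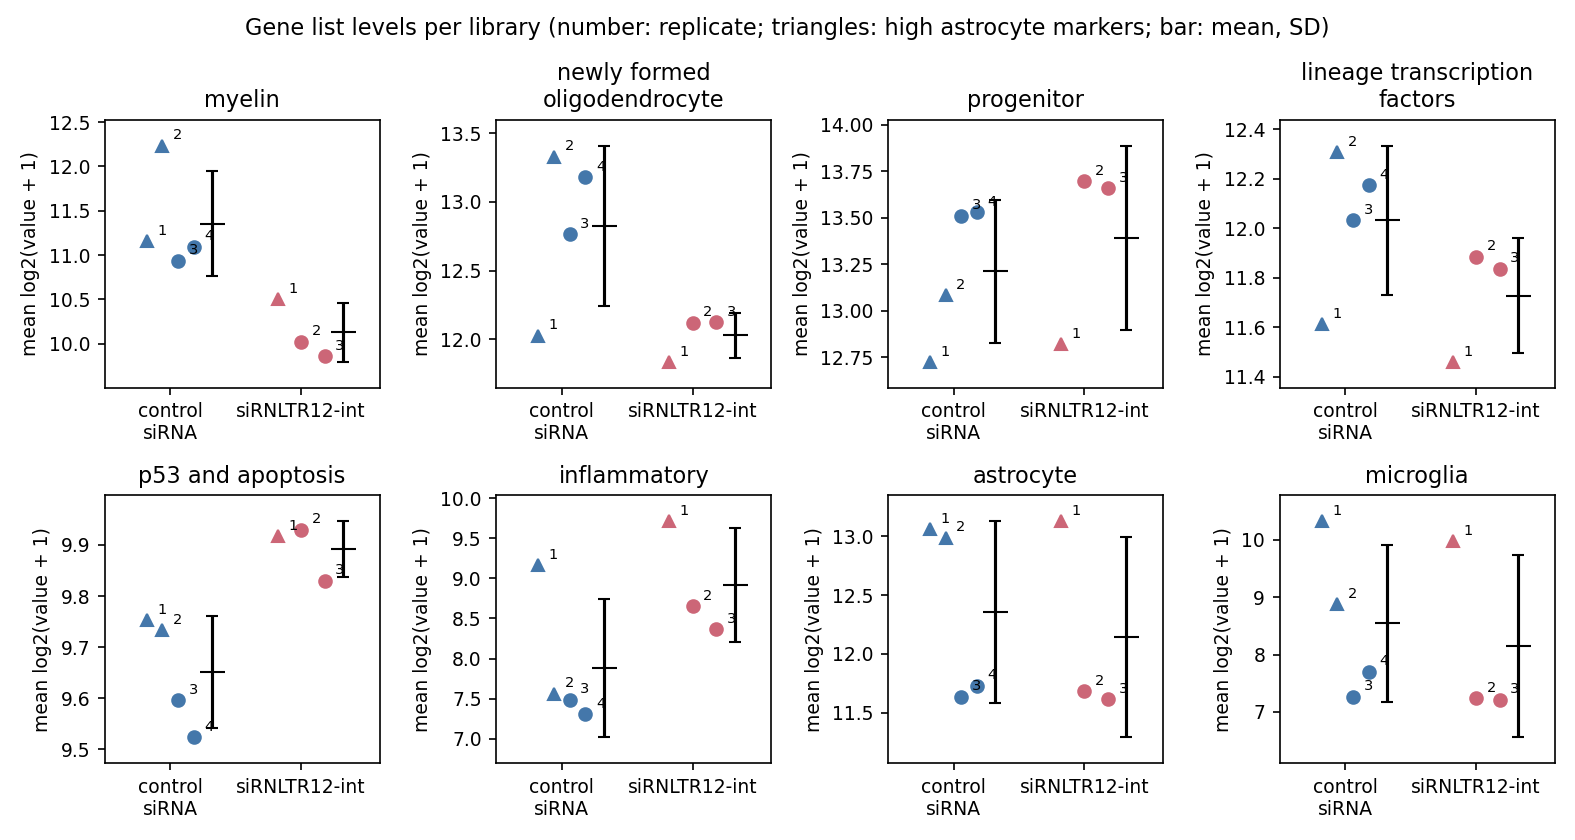
Level of 8 gene lists, the mean log2(normalised count + 1) of the members, for each library, with the replicate number beside each point, triangles for the 3 libraries high in astrocyte markers, and a bar for the group mean and SD. The myelin level lies between 9.86 and 10.51 in the siRNLTR12-int libraries and between 10.94 and 12.24 in the controls, whereas the astrocyte and microglia levels separate 3 libraries from 4 irrespective of the siRNA.

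Gene by gene, the number of calls differed between tools. Limma called 0 of 18225 genes, with 606 higher and 543 lower at an unadjusted p under 0.05, and edgeR on the recovered reads called 0, with 1165 at an unadjusted p under 0.05. In the authors' deposited table (DESeq2) 72 genes rose and 69 fell, and 38 and 63 of them were marked as up and down with an absolute log2 fold change above 1. DESeq2 on the recovered reads gave the same 141 calls. Besides myelin genes, the falls named from that table by the rule for named genes include Nipal4 (log2 -3.62, DESeq2 adjusted p = 0.00147). The fall of Nipal4 was enlarged by control replicate 2, at 986 normalised counts against 143 to 234 in the other controls. Besides Gdf15, given above, the rises that this rule names, with a mean of at least 100 normalised counts, are those of Siglec10, a sialic acid receptor of immune cells, Igfbp3, a binding protein of insulin-like growth factors, the secreted protease Adamts1, the opioid precursor Penk, the AP-1 factor Fosl1, the ephrin receptor Epha2 and the adaptor subunit Ap1s3 (log2 3.72, 2.38, 2.07, 2.03, 1.72, 1.71 and 1.70, DESeq2 adjusted p from 4.9e-06 to 0.036). Siglec10 was low in controls, at 1.77 to 53.6 normalised counts, and at 493, 129 and 92.7 in siRNLTR12-int replicates 1 to 3. Its mean thus rests largely on siRNLTR12-int replicate 1, a library also high in microglia markers. Igfbp3 had 1424 ± 741.5 (SD, n = 4) normalised counts in controls and 7423 ± 1346 (SD, n = 3) after the siRNA. The DESeq2 count became 552 without control replicate 1, 49 without control replicate 4, and 520, 9 and 15 without siRNLTR12-int replicates 1, 2 and 3.

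In the 4 libraries low in astrocyte markers, a comparison added after the data were seen, limma called 732 genes higher and 486 lower. Mbp, Mag and Mobp fell (log2 -2.47, -2.52 and -3.03, limma adjusted p = 0.00757, 0.00757 and 0.000932), Cdkn1a and Igfbp3 rose (log2 1.37 and 2.35, limma adjusted p = 0.00786 and 0.00757), and the progenitor gene Cspg5 rose (log2 0.90, limma adjusted p = 0.0136). Sox10 did not pass there (log2 -0.32, limma adjusted p = 0.155). The other 3 libraries, which share no sample with these 4, had the same direction in 1062 of the 1218 called genes (87.2%), against 58.5% of all tested genes. Their change is siRNLTR12-int replicate 1 minus the mean of control replicates 1 and 2. Those 2 controls themselves differed in the called genes (replicate 2 minus 1, median 1.01 in the lower and -0.42 in the higher genes). Part of the agreement may thus rest on control replicate 2. The spread in the 4-library test rests on 2 libraries per group, and siRNLTR12-int replicates 2 and 3 were the most alike of all pairs (r = 0.991 across genes, which are not independent replicates).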

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

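All tests of explanations in this part were chosen after the result was seen, except the search for outlying control libraries.

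Among 71 results checked for a control library far from the other 3 (the gap to the nearest divided by the range, above Dixon's 95% critical value), 6 stood out, where chance gives about 1 in 20, or 3.6. Control replicate 1 was lowest for Sox10 (0.83) and highest for Il1b (0.851) and for the level of the inflammatory list (0.862). Control replicate 2 was highest for the level of the myelin list (0.834) and for Elovl7 (0.926) and lowest for Samd4a (0.989).

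The myelin genes were lower in the siRNLTR12-int libraries. A smaller share of oligodendrocyte lineage cells as the whole cause is argued against by the level of the myelin list relative to the mean of Sox10, Olig1 and Olig2, which still differed by -1.02 with a standard error of 0.12 when the split of the libraries was a block; a smaller share of mature cells within the lineage is left open by this test. Control replicate 2 alone is argued against as well, since without it the level differed by -0.93, with no overlap and a larger group SD of 0.33. A general response to this siRNA cannot be told apart from loss of its target, because the series holds a single siRNA and no rescue, and the stress list differed by 0.37 in the same libraries. The camera p of the myelin list, 1.07e-10, was the smallest of the 35 splits (1 of 35, next 2.4e-09). That rank is not adjusted for the other lists ranked in this way, and it assumes that the 7 libraries are exchangeable. Astrocyte markers set libraries apart irrespective of the siRNA, so they cannot be taken as exchangeable. The rank therefore does not exclude chance. The splits were run without the mean-variance trend, and with it the real camera p was 2.45e-11. Among the 18 splits within the blocks of the library split, the level differed by -1.12 in the real one. It differed by 1.21, a larger size than in the real one, in the split with control replicates 2, 3 and 4 on 1 side. These are too few splits for a share under 5%. The biological explanation, loss of RNLTR12-int, remains a hypothesis.

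Control replicates 1 and 2 and siRNLTR12-int replicate 1 stood apart from the other 4 libraries. Depth as the cause is argued against by the 4 libraries of 41506220 to 48187822 reads, among which the astrocyte level still differed by 1.47, with a smallest gap of 1.42. A scaling factor per library is argued against by the astrocyte level minus the mean level of all tested genes, in which such a factor cancels apart from the pseudocount, and which still differed by 1.26, with a smallest gap of 1.16. More astrocytes in those cultures is a candidate explanation: 18 of 22 astrocyte markers, Gfap, Aqp4 and Slc1a3 among the abundant ones, were higher in each of the 3 libraries than in each of the other 4, against 18.6% of all genes, although Vim, Sox9 and Id3 on that list are also expressed by progenitors. The 3 libraries were set apart by these same markers, so that count gives no independent support. The same 3 libraries had 18 of 21 microglia markers and 31 of 33 interferon genes higher and 21 of 25 cholesterol genes lower, so that a difference in culture state may go with one in cell types; no biological explanation from the design was tested.

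The number of calls depended on the test. With DESeq2, 10 of the 35 splits called as many genes as the real one (141, highest other 5784), so chance cannot be excluded for that count. With limma the real split called 0, which all 35 splits reach, and the highest other called 4627. Those highest counts come from the split that separates control replicates 1 and 2 and siRNLTR12-int replicate 1 from the rest, which points to a structure of the samples, and with that split as a block DESeq2 called 418 genes higher and 273 lower, a count that 2 of the 18 splits within the blocks reached (highest other 2358), too few splits for a share under 5%. Whether spread added by that structure may account for the limma count stays open: limma called 1218 genes in the 4 libraries although they are fewer, and 0 and 0 in the other 2 splits of those 4, but with the split as a block in all 7 it called 0 (2550 at an unadjusted p under 0.05, smallest adjusted p = 0.0588) and edgeR called 1.

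For the other called lists, the number of the 35 splits with a camera p as small as the real one was 4 for newly formed oligodendrocyte markers (real 1.33e-09, smallest other 2.61e-16), 2 for sphingolipid synthesis (0.00058, 0.000217), 21 for cholesterol (0.0113, 5.21e-10), 28 for cell cycle (0.028, 2.54e-18) and 6 for inflammatory signalling (1.36e-07, 7.78e-16). It was 3 for the integrated stress response (5.1e-05, 8.08e-07), 2 for p53 and apoptosis (0.00057, 0.000167), 25 for ribosomal proteins (0.0107, 6.81e-14) and 10 for the cytoskeleton (0.00103, 6.16e-08). These p-values were computed without the mean-variance trend, a setting in which the cell cycle list did not pass (camera adjusted p = 0.0645). Chance could not be excluded for any of these 9 lists.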

How the results depend on the processing

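The block for the library split, the astrocyte covariate, the 4-library fit and the further DESeq2 fits were chosen after the data were seen; the other alternatives were planned. Limma called 0 genes under the other pseudocounts, filters, rescalings, no trend, the replicate block, the split block and the covariate, and with edgeR. It called 456 higher and 383 lower with array weights, 732 and 486 in the 4 libraries low in astrocyte markers, and DESeq2 called 72 and 69; leaving out each library gave 0 to 1 higher and 0 to 1 lower. The DESeq2 counts became 418 and 273 with the split block, 910 and 822 in the 4 libraries, and 38 higher at an absolute log2 of at least 1; leaving out each library gave 5 to 295 higher and 4 to 324 lower. Replicate numbers matched the samples only in part: deviations correlated at 0.746, -0.191 and 0.632 for numbers 1, 2 and 3. Across the siRNA groups, numbers 1 and 3 matched their own number best and number 2 did not. A pairing by number is therefore neither shown nor excluded. With the replicate block limma called 0 genes, DESeq2 called 78 and 98, and the progenitor, astrocyte, microglia and fatty acid lists passed (adjusted p = 0.0347, 0.00409, 0.0014 and 0.038), while cell cycle did not (0.122). With an estimated correlation the myelin, newly formed, cholesterol and sphingolipid lists had adjusted p = 0.638, 0.638, 0.899 and 0.663, and with fry 0.353, 0.436, 0.837 and 0.562. Both of these settings were run without the mean-variance trend. The cholesterol list lost its call with the split block (0.111), the covariate (0.0636) and the 4 libraries (0.296), and ranged from 7.32e-05 to 0.613 with a library left out. The lineage factor list passed with edgeR (0.0296) and ranged from 0.00448 to 0.893, and the progenitor list from 0.00737 to 0.821.

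Lists that turned direction were cell cycle with array weights (0.0279) and in the 4 libraries (0.00257), interferon with pseudocount 8 (0.996), a minimum mean of 50 (0.943), TMM (0.979), array weights (0.261) and the replicate block (0.122), neuron with a minimum mean of 50 (0.992), and vascular and mitochondrial with array weights (0.716 and 0.884). With the split block, astrocyte (0.758), microglia (0.879), neuron (0.879), gap junction (0.877) and post-transcriptional (0.877) turned, as did astrocyte (0.946), neuron (0.946), gap junction (0.934) and post-transcriptional (0.934) with the covariate and gap junction (0.953) in the 4 libraries. With each library left out the adjusted p ranged from 0.000968 to 0.964 for astrocyte, 3.49e-06 to 0.328 for cell cycle, 0.214 to 0.996 for vascular, 0.000578 to 0.621 for microglia, 0.347 to 0.774 for mitochondrial, 0.0491 to 0.743 for neuron, 0.118 to 0.928 for post-transcriptional and 0.000394 to 0.3 for interferon. Cenpf turned to 0.04 with array weights and, with Bub1b (0.02), to 0.09 in the 4 libraries, and Sox10 ranged from -0.84 to 0.25 with a library left out. The cause of these changes was not tested. The 23 list levels kept to within 1 SD under every alternative run for them. That bound is wide, since the SD of the microglia level was 1.37 in controls and 1.59 after the siRNA. It therefore does not show that the differences between the groups were stable.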

Other observations

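The lists of early response and NRF2 genes, and the test of each as a group, were chosen after the calls were seen; the test along the axis between control cultures was set before its value was computed, when the myelin levels of the libraries were already known.

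Early response genes of the ERK and AP-1 pathway, which cells switch on within minutes to hours of growth factor or stress signals, had a positive log2 difference in 30 of 30 listed members, with a median of 1.17 (camera p = 3.26e-23 with limma at the preset correlation, p = 0.0194 with an estimated correlation). In the authors' deposited table (DESeq2) 8 of them rose, Dusp1, Trib1, Lif, Epha2, Fosl1, Fosl2, Errfi1 and Dusp4. The list was written with some of these calls already seen, so it was tested again over the 22 members outside the calls. All 22 were positive, with a median of 0.90 (camera p = 1.69e-13 with limma, p = 0.0363 with an estimated correlation), and 18 were higher in the 4 libraries low in astrocyte markers (limma). The second test used the same libraries as the calls, so it does not remove the selection. The level of these 22 differed by 0.92, but control replicate 1 (10.04) came close to the siRNLTR12-int libraries (10.18 to 10.38), the exact permutation p was 0.0571, and 2 of the 35 splits gave as small a camera p (smallest other 9.03e-19), so chance cannot be excluded. Higher ERK or AP-1 signalling after this siRNA is a hypothesis that members picked from this list after their values were seen cannot test. The ERK targets Dusp6, Spry4 and Etv4 were at 1.41, 1.56 and 1.36, without passing in the authors' table (DESeq2 adjusted p = 0.058, 0.174 and 0.203). Other members were smaller, with Egr1 at 0.68, Myc at 0.40, Fos at 0.34, Spred1 at 0.29 and Jun at 0.25. NRF2 target genes, tested in the same way because Hmox1 and Txnrd1 were among the authors' higher calls, did not move as a group (camera p = 0.804 over 16 members with limma, median -0.03).

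A further hypothesis is that the siRNLTR12-int cultures may stand at an earlier stage along the axis that separates control cultures. It was tested without shared libraries, by correlating across genes the change in the 4 libraries low in astrocyte markers with control replicate 2 minus control replicate 1. Pearson's r was -0.242, past the bound of -0.2 set beforehand, and Spearman's rho was -0.19, which is not; genes are not independent replicates, and each side rests on few libraries. Genes lower in the 4 libraries had a median of 1.01 in control replicate 2 minus control replicate 1 and genes higher there a median of -0.42. Markers of other cells differed between these 2 control libraries about as much as the myelin list (median 1.32): microglia by -1.59, inflammatory genes by -1.49, vascular and fibroblast markers by -1.27 and neuron markers by 1.06. The axis can therefore not be read as maturation alone, and a stage of maturation stays open.

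Outside the naming rule, LOC103689999 had 175.1, 958.6, 502.5 and 278.5 normalised counts in controls against 18.27, 10.13 and 16.92 after the siRNA, and AABR07012291.1 was at 0 in 3 controls and at 3.55 in the other, against 65.78, 91.14 and 56.41. Both were chosen after their values were seen and did not pass with limma (adjusted p = 0.605 for each), whereas in the authors' deposited table they differed by -4.98 and 7.13 on the log2 scale (DESeq2 adjusted p = 6.22e-12 and 1.11e-07).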
